A study of Caenorhabditis elegans with 11 samples.

How the data were processed

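The deposited files held 11 droplet libraries of dissociated whole C. elegans, made by the authors from 6 harvests of a single ageing population. Per the labels' protocols, worms of strain CF4596 were fed antibiotic-killed bacteria, opened with a reducing detergent buffer and digested with pronase, and polyA RNA was captured on a 10x Genomics chip. Per the file headers, the authors processed each channel with Cell Ranger 3.0.0; the deposited values are raw UMI counts per gene and cell barcode. The genome build, annotation and handling of reads that map to several genes are not given in the sources used here, so no gene positions were used. Members of multicopy families (ribosomal RNA, histones, major sperm proteins, vitellogenins, small heat shock proteins) share near-identical sequence, and their counts are uncertain to that extent. The smallest barcode held 500 UMIs, so barcodes had been filtered before deposit. The files held 30166 genes, 78027 barcodes and 259673582 UMIs. Gene names are those in the files.

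Barcodes with at least 300 UMIs and at most 30% of UMIs from genes of the mitochondrial genome were kept; 507 barcodes exceeded the second limit and none fell under the first. Doublets were scored per library by an implementation of the Scrublet procedure written for this work (30 principal components, 2 simulated doublets per cell). Its automatic threshold called 5 doublets, 0.00641% of the barcodes, far under the expected rate, so an alternative removed the highest scores at 0.8% per 1000 barcodes. The remaining 77515 cells were scaled to 10000 UMIs, log-transformed and reduced to 40 principal components of 2000 variable genes. They were clustered by the Leiden method in python-igraph 0.11.9 (modularity, resolution 2, 5 iterations) on a graph of 15 nearest neighbours weighted by Jaccard overlap. Clusters of at least 10 cells, 124 in all, were named from 23 marker lists, 5 of them for neuron subtypes. A class was given where at least 3 markers were raised at least 2-fold and seen in at least 10% of the cells, the mean log2 fold was at least 0.5 (1 if only 3 markers were raised) and the next class lay 0.3 lower. The pseudocount was 10 CPM, and the 10 leading genes at 50 CPM or more were checked against markers of other classes. These naming thresholds were set after the clusters had been seen. In all, 99 clusters took 16 class names and 25 clusters with 20378 cells were left unnamed, 18 of them for too few markers. A class name means cells like that class by markers. The marker lists of the germline and of oocytes and early embryos named a single class, the germ line-like cells.

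The unit of replication was the harvest: counts of a class were summed over its cells and over both channels. A class was tested with at least 20 cells per harvest in at least 5 harvests, and the 8 largest such classes were taken. Neurons, hypodermis, seam cells and intestine had 5 harvests, without day 15, and the other 4 classes had 6. Age trends were fitted per gene with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F-test of the slope on age in days) and adjusted by Benjamini-Hochberg at 0.05. Slopes are log2 units per day with the default prior count of edgeR. A prior count of 2 was set for limma-trend. Levels of genes in a class by harvest are CPM with TMM scaling. The CPM of gonad markers and the levels relative to the highest class are without TMM scaling. The 38 gene lists were tested on the same fit with camera in limma 3.58.1 (preset correlation 0.01), adjusted over 295 combinations of a list of at least 5 genes and a class, of which 146 passed. With an estimated correlation 0 of the 295 passed, the smallest adjusted p being 0.4865. The fry test called 3, each with an adjusted p of 0.0417: the respiratory chain in germ line-like cells and in the pharyngeal epithelium, and lysozymes in pharyngeal muscle. Differences between the 4 largest classes were tested with a class-by-age term and a harvest block, and for lists by exact permutation of the ages. Each later day was set against day 1 with the channels as samples (edgeR, log2 fold change of at least 1). Shares were tested by two-sided exact permutation of all 720 orders of 6 harvests, with a pseudocount of 0.5 cells. Genes per cell were tested over all orders of a class's harvests, 720 with 6 harvests and 120 with 5. The number of genes trending in at least 4 classes was set against 100 drawn orders of the ages.

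Depth set the precision. Germ line-like cells were fewest on day 1, with 58 cells, 444051 UMIs and a floor of 8.14 CPM, so each comparison of that class with day 1 rests on those cells. The last harvest held 1026165 UMIs in germ line-like cells, 79886 in body wall muscle, 125568 in pharyngeal muscle and 42160 in the pharyngeal epithelium on day 15, and 2535133 in neurons, 247107 in hypodermis, 56163 in seam cells and 30730 in intestine on day 11. A level of 3 counts, taken as the floor, was 2.37 CPM in germ line-like cells on day 15 and 73 CPM in the intestine on day 11. The tests were tested on simulated data with the dispersion of each class: of genes changed 32-fold over the series, 93.9% were recovered in germ line-like cells, 76.6% in body wall muscle, 68.2% in neurons and 36.9% in hypodermis, and 0% of genes changed 2-fold in any class.

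The text names genes by a rule: in the 4 largest classes the 12 steepest rising and 12 steepest falling genes, and 5 each in the others, with an adjusted p under 0.05, a mean log2 CPM of at least 5 and a CPM of at least 0.1 of that in the highest class. Where none passed, the 3 with the smallest p each way are given as values. It also names up to 4 members with the smallest p per described list, 10 genes each way across classes, 13 genes followed in every class and up to 4 gonad markers per list. The tests, gene lists, marker lists, naming rule for genes and most alternatives were fixed before the data were examined. The alternatives were RLE factors or library size alone in place of TMM, no filter on low counts, DESeq2 1.42.0 or limma-trend in place of edgeR, the log2 of the age, younger against older harvests, each harvest or channel left out, the channels as samples with and without a block, other limits on UMIs, mitochondrial share and doublets, a coarser clustering, thinned counts, and other set tests. Unnamed cells and the other 8 classes were counted but not tested for gene trends. Of these, coelomocytes (877 cells), pharyngeal gland (576) and glia (465) met the size limits but were smaller than the 8 classes taken. Other software was R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-image 0.26.0 and matplotlib 3.10.9.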

Results

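Single-cell transcriptomes were measured in whole adult Caenorhabditis elegans at 6 ages, on adult day 1 and on days 3, 5, 8, 11 and 15. The worms carried gon-2(q388ts), a temperature-sensitive allele of a TRPM channel gene that gonad precursor cells need to divide, and daf-2::AID, an insulin/IGF-1 receptor gene tagged for auxin-induced degradation. A single population was aged, and the cells of each harvest from day 1 to day 11 were loaded on 2 channels of a droplet chip and those of day 15 on 1 channel. The channels of a harvest are technical repeats, so the 6 harvests were the independent units and no age had a biological replicate. Total UMIs per library were 26607348 and 27956883 on day 1, 30082476 and 29591926 on day 3, 25256143 and 28682703 on day 5, 31122709 and 36393671 on day 8, 11721353 and 9971941 on day 11 and 2286429 on day 15. The median barcode held 1551 to 1914 UMIs from day 1 to day 8 and 1207 to 1268 on days 11 and 15. After filtering, 77515 cells remained, from 22544 on day 1 to 863 on day 15.

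Neurons were the largest class on day 1 and germ line-like cells the largest on day 15. Neurons made up 54.1% of the cells on day 1, 30.6% on day 5, 40.6% on day 8, 20.0% on day 11 and 1.16% on day 15. Germ line-like cells were 0.257% of the cells on day 1 (95% exact binomial interval 0.195 to 0.333%), 4.59% on day 3, 12.8% on day 5, 11.25% on day 8, 18.6% on day 11 and 34.4% on day 15 (31.3 to 37.7%). Pharyngeal gland cells were 0.617% on day 1, 0.142% on day 5 and 10.1% on day 15, and pharyngeal muscle 2.48%, 0.577% and 10.4%. Seam cells, the lateral epidermal cells, were 5.01% on day 1, 5.36% on day 5 and 0.659% on day 11. The slope of the logit share per day was -0.27 for neurons (exact permutation p = 0.00833, adjusted p = 0.1, n = 6 harvests), -0.24 for seam cells (exact p = 0.0125, adjusted p = 0.1) and 0.30 for germ line (exact p = 0.0236, adjusted p = 0.121). No class share passed the two-sided exact permutation test over all 720 orders of the ages after adjustment. Without day 15, when 10 neurons were captured, the neuron slope was -0.12 (exact permutation p = 0.0917, n = 5 harvests), and without day 1 the germ line slope was 0.17. Of all cells, 26.3% could not be named, from 20.7% on day 1 to 34.5% on day 3.

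**Figure D1:**
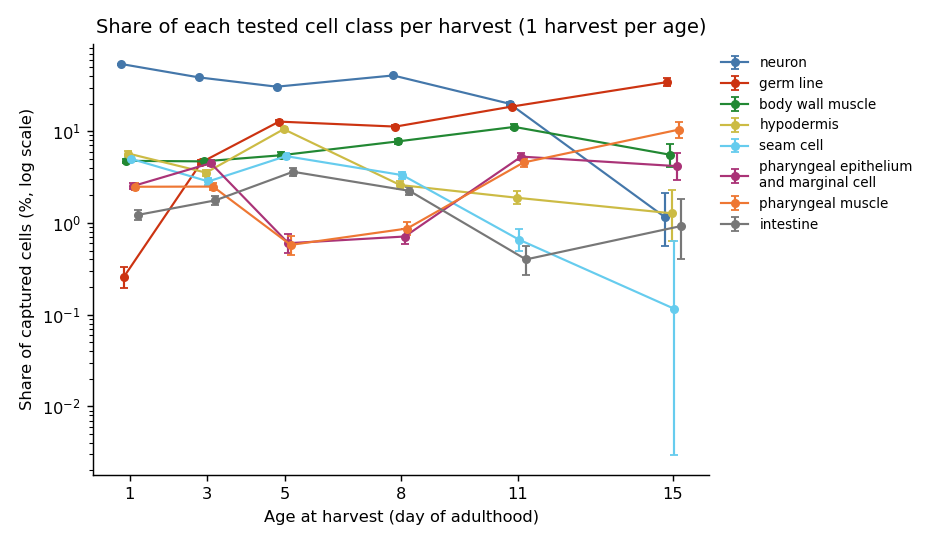
Share of captured cells (%, log scale) against age at harvest (day of adulthood) for the 8 tested cell classes, with 95% exact binomial intervals as error bars and 1 harvest per age. The neuron line ends at 1.16% and the germ line ends at 34.4% on day 15.

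Transcripts of germ cells, oocytes and sperm were present in these gon-2 mutants. Over all cells of a harvest, mex-5, which encodes a zinc finger protein of germ cells and embryos, was at 4.06 CPM on day 1, 262 CPM on day 5 and 394 CPM on day 15. The germ granule genes glh-1 and pgl-1 were at 36.7 and 12.8 CPM on day 1 and at 201 and 165 CPM on day 15. The eggshell gene cpg-2 was at 4.90 CPM on day 1 and 1135 CPM on day 5, and over all harvests at 2299 CPM in germ line-like cells against 51.9 CPM in neurons. The major sperm protein gene msp-36 was at 0.917 CPM on day 1 and 126 CPM on day 5, and at 6059 CPM in sperm-like cells against 2.02 CPM in germ line-like cells. Of the somatic gonad markers, the innexin gene inx-9 was at 12.1 CPM on day 1, 42.0 CPM on day 5 and 3.12 CPM on day 15, and inx-8 at 7.93, 73.4 and 8.01 CPM. The other 2 were lower on day 5 than on day 1, lim-7 at 46.6 and 13.2 CPM and ceh-18 at 35.0 and 13.3 CPM. lim-7 was at 4.05 CPM in somatic gonad-like cells against 65.4 CPM in neurons, so its level is not specific to the gonad here. The eggshell genes perm-2 and perm-4 were at 464 and 396 CPM in neurons against 67.1 and 59.45 CPM in germ line-like cells, so their levels are not specific to germ cells here. These levels were not tested for a trend, and transcript levels do not check the point allele.

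**Figure D2:**
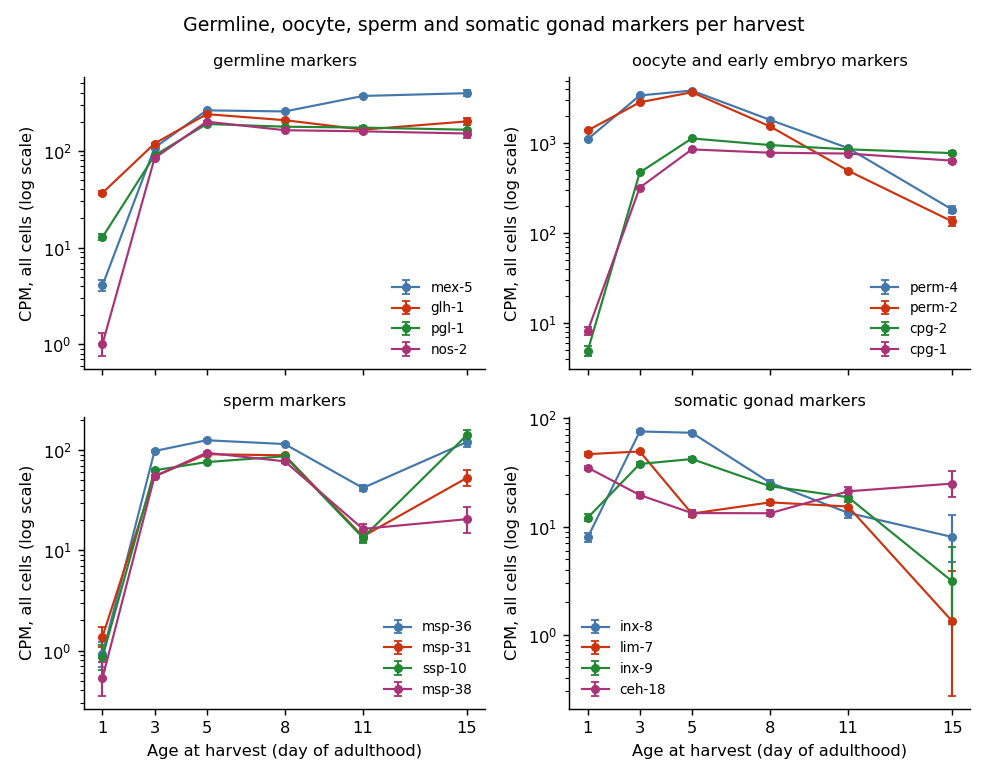
Level (CPM over all cells of a harvest, log scale) of 4 markers each of germ cells, oocytes and early embryos, sperm and somatic gonad against age at harvest (day of adulthood), with 95% counting intervals as error bars and 1 harvest per age. mex-5 goes from 4.06 CPM on day 1 to 394 CPM on day 15 and msp-36 from 0.917 to 126 CPM between days 1 and 5.

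In germ line-like cells, most genes of the cytosolic ribosome fell with age, and the kinase genes mpk-1 and src-1 were among those that rose. The first harvest held 58 such cells. rpl-7A (WBGene00004419), of the large ribosomal subunit, fell by 0.21 log2 per day (standard error 0.03, adjusted p = 0.00855, n = 6 harvests), from 8432 to 933 CPM. rack-1 (WBGene00010556), a scaffold on the small subunit, fell by 0.22 per day (standard error 0.03, adjusted p = 0.0101), from 6528 to 609 CPM. mpk-1 (WBGene00003401), the ERK MAP kinase of oocyte maturation, rose by 0.21 per day (standard error 0.03, adjusted p = 0.00779), from 16.3 to 258 CPM. src-1, a Src family tyrosine kinase, rose from 8.14 CPM, the level of 3 counts on day 1, to 93.8 CPM (slope 0.22, adjusted p = 0.00814), and zyg-11, a substrate receptor of a cullin ubiquitin ligase, from 24.4 to 495 CPM (slope 0.18, adjusted p = 0.0486). Other steep rises were rrn-4.2 (a ribosomal RNA gene, slope 0.44), F13B12.6 (0.27), his-65 (a histone, 0.25), Y41C4A.29, dhs-13, crml-1, C09H10.5, gly-9 and Y92H12BR.3. The steepest falls were the mitochondrial genome's nduo-6 (slope -0.31, 5050 to 199 CPM) and ctc-3 (slope -0.24), the linker histone gene hil-2 (slope -0.28, 404 to 27.6 CPM), rbm-3.2, C05C10.7, the ADP/ATP carrier gene ant-1.1 (slope -0.22), rpl-35, rps-8, rpl-11.1 and F35D11.4. The level of rrn-4.2 in germ line was below that of day 1 on days 3, 5 and 8 (log2 fold change -2.73, -1.99 and -1.27), and its slope was -0.0923 with days 11 and 15 left out. In all, 778 genes rose and 625 fell among 10608 tested.

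Of 79 cytosolic ribosomal proteins in germ line-like cells, 68 fell and 0 rose over all genes tested. In this list 74 fell adjusted over the list alone (mean slope -0.15, camera adjusted p = 2.06e-44; adjusted p = 0.50 with an estimated correlation). In cells of at most 3000 UMIs the mean slope of these genes was -0.086. Among them, rps-22 (slope -0.19), rps-8, rpl-12 (-0.20) and rps-9 (-0.18) had the smallest p. Of 49 nuclear-encoded respiratory chain genes, 16 fell, among them nuo-3 (slope -0.19), asb-2, atp-2 and ucr-2.3. For this chain 25 fell and 1 rose adjusted over the list alone (camera adjusted p = 2.69e-07; adjusted p = 0.50 with an estimated correlation). Of the 12 genes of the mitochondrial genome 7 fell, and 9 adjusted over the list alone (camera adjusted p = 2.37e-08; adjusted p = 0.49 with an estimated correlation). The median share of mitochondrial UMIs per cell was 2.44% on day 1 and 0.499% on day 15. Of 38 translation factors 9 fell and 3 rose. Among these, adjusted over the list alone, 14 fell and 3 rose (mean slope -0.04, camera adjusted p = 0.00185; adjusted p = 0.65 with an estimated correlation). The camera adjusted p of translation factors was 0.0783 with library size only, and the mean slope was 0.0098 in cells of at most 3000 UMIs. Of 23 chaperones 6 fell, among them pfd-6, pfd-3 and hsp-1, and 3 rose, among them unc-45 (slope 0.18). Chaperones adjusted over the list alone numbered 10 that fell and 3 that rose (mean slope -0.04 but 0.0041 with library size only, camera adjusted p = 0.00281 and 0.0696; adjusted p = 0.58 with an estimated correlation). Chaperones had a mean slope of -0.0035 in cells of at most 3000 UMIs (camera adjusted p = 0.772). Of 31 splicing genes 6 fell, and 7 adjusted over the list alone (mean slope -0.04 but 4e-04 with library size only, camera adjusted p = 0.00492, 0.126 with library size only and 0.114 without day 15; adjusted p = 0.65 with an estimated correlation). Of 28 autophagy genes, atg-7 and epg-6 rose over all genes and 1 adjusted over the list alone (mean slope 0.04, camera adjusted p = 0.00523, 0.270 without day 1; adjusted p = 0.69 with an estimated correlation). The autophagy slope was 0.0036 in cells of at most 3000 UMIs (camera adjusted p = 0.677). Of 41 histones, his-37, his-35, his-68 and 2 others fell and his-65 rose, as they did adjusted over the list alone. Histones as a list did not pass camera (adjusted p = 0.553), its mean slope being -0.003 and its median 0.012. They did pass in cells of at most 3000 UMIs (mean slope -0.1153, camera adjusted p = 8.28e-05). Of 67 mitochondrial ribosomal proteins 10 fell and 2 rose. Within them 13 fell and 3 rose adjusted over the list alone (mean slope -0.02 but 0.0182 with library size only and 0.0288 in cells of at most 3000 UMIs, camera adjusted p = 0.0146, 0.0911 without day 1 and 0.0625 without day 11; adjusted p = 0.66 with an estimated correlation). Of 33 proteasome genes 3 fell and 2 rose. Proteasome genes adjusted over the list alone numbered 4 that fell and 2 that rose (mean slope -0.03 but 0.0108 with library size only, camera adjusted p = 0.0198, 0.0572 without day 11 and 0.402 without day 15; adjusted p = 0.75 with an estimated correlation). The proteasome slope was -0.0128 in cells of at most 3000 UMIs (camera adjusted p = 0.621).

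The number of genes called in germ line-like cells depended on the harvests, the cells and the scaling taken. The count of trending genes was 2959 without day 1, 702 without day 3, 563 without day 5, 685 without day 8, 90 without day 11 and, by edgeR, 0 without day 15 (2064 at an unadjusted p under 0.05). Of the genes called with all harvests and tested again, 1369 of 1369 kept the sign of the slope without day 15 and 1362 of 1375 with days 11 and 15 left out. These genes were chosen by their slope over all harvests and the refits reuse most harvests, so a kept sign is no independent support. The median germ line-like cell held 7805 UMIs on day 1 and 1289 on day 15; in cells of at most 3000 UMIs 535 genes rose and 492 fell among 6456 tested, and with library size only 1913 rose and 383 fell.

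**Figure D3:**
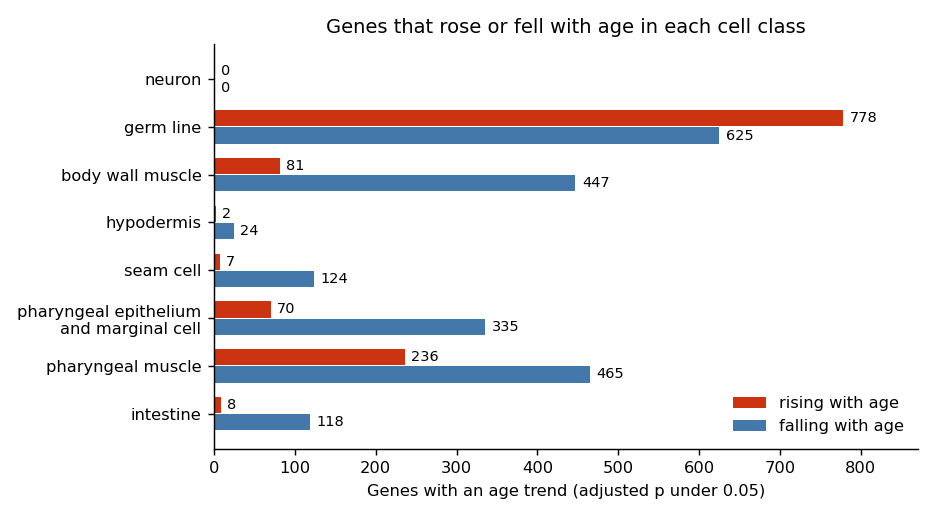
Number of genes (horizontal axis) whose level rose or fell with age at an adjusted p under 0.05 in each of the 8 tested cell classes (vertical axis). Germ line-like cells have 778 rising and 625 falling genes and neurons 0.

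In body wall muscle, some genes of the sarcomere and of energy metabolism fell with age. mlc-1, a myosin light chain gene, fell from 1397 to 36.3 CPM (slope -0.31), and csq-1, the calcium-binding calsequestrin of the sarcoplasmic reticulum, from 2128 to 189 CPM (slope -0.25). unc-54 (WBGene00006789), the major myosin heavy chain of body wall muscle and a marker used to name this class, fell by 0.23 log2 per day (adjusted p = 0.0256, n = 6 harvests), from 7495 to 676 CPM. F46H5.3 (WBGene00018519), an arginine kinase gene, fell by 0.42 per day (standard error 0.05, adjusted p = 0.00637), from 13610 to 159.9 CPM, and tag-18 by 0.36 per day (standard error 0.05), from 1552 to 21.8 CPM. The cadherin gene hmr-1 rose by 0.22 per day (standard error 0.03, adjusted p = 0.00975), from 25.6 to 239.9 CPM. egas-3 (slope -0.75), srb-16 (-0.64), W10C8.5, Y43F8C.18 and ZC239.5 fell to 0 CPM on day 15, where 3 counts, taken as the floor, were 21.8 CPM; here and elsewhere the fitted slope of a gene at 0 in the last harvest depends on the prior count, and levels at or under the floor rest on at most 3 counts. Other steep falls were D1086.12, Y69E1A.5, ZC412.3, glb-10 and C17C3.1. Of the genes that fell, D1086.12 (log2 fold change 3.66), Y69E1A.5 (1.54), W10C8.5 (1.32) and C17C3.1 (1.01) were above day 1 on day 3, when 52.2% of the muscle cells came from a cluster led by D1086.1 that led on no other day. Other steep rises were Y40B10B.1, F46A8.13, Y58A7A.3, rrn-4.2, F35G2.1, gem-4, rrf-2, lfor-1, K09F6.9, byn-1 and fbxa-24. In all, 81 genes rose and 447 fell among 9536 tested.

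Of 47 sarcomere genes in body wall muscle, 21 fell and 0 rose. For the sarcomere 29 fell adjusted over the list alone (mean slope -0.14, camera adjusted p = 3.05e-14; adjusted p = 0.52 with an estimated correlation). The class markers clik-1 (slope -0.29, 6045 to 305 CPM) and tnt-2 (slope -0.29, 3538 to 167 CPM) were among them. Of 47 nuclear-encoded respiratory chain genes 30 fell, among them asb-2 (slope -0.28, 563 to 29.1 CPM), ucr-2.1, atp-3 and asg-2. Respiratory chain genes numbered 37 that fell adjusted over the list alone (camera adjusted p = 3.7e-19; adjusted p = 0.49 with an estimated correlation). Of 19 TCA cycle genes 11 fell, among them dld-1, idhg-2, suca-1 and sucl-1. TCA cycle genes numbered 17 that fell adjusted over the list alone (camera adjusted p = 4.87e-13; adjusted p = 0.49 with an estimated correlation). Of 20 glycolysis genes 10 fell, among them gpd-2 (1162 to 131 CPM), aldo-2, tpi-1 and pgk-1. Glycolysis genes numbered 15 that fell adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.50 with an estimated correlation). Of the 12 genes of the mitochondrial genome 4 fell, and 11 adjusted over the list alone (camera adjusted p = 4.16e-08; adjusted p = 0.50 with an estimated correlation). The median mitochondrial share was 3.27% on day 1 and 0.623% on day 15. Of 14 small heat shock proteins, hsp-12.3 (slope -0.31, 9245 to 342 CPM) and hsp-25 fell over all genes. Small heat shock proteins numbered 3 that fell adjusted over the list alone (camera adjusted p = 0.00267, 0.149 without day 15; adjusted p = 0.50 with an estimated correlation). The 79 cytosolic ribosomal proteins had a mean slope of -0.05 (camera adjusted p = 0.0365; adjusted p = 0.85 with an estimated correlation) that was 0.02 with library size only. That call ended without any of days 5, 8, 11 and 15 (camera adjusted p = 0.155, 0.0598, 0.115 and 0.976).

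The count of 528 trending genes in body wall muscle was 274 without day 8, 58 without day 11 and 61 without day 15. With library size only, 361 genes rose and 291 fell.

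In the hypodermis, some cuticle collagen genes fell with age. col-80 (WBGene00000656) fell by 1.33 log2 per day (standard error 0.16, adjusted p = 0.0385, n = 5 harvests), from 22240 CPM on day 1 to 3.12 CPM on day 11. col-178 fell from 24520 to 40.6 CPM (slope -0.93), T13F3.6 from 2667 to 3.12 CPM and col-160 from 12270 CPM to 0, where the floor of 3 counts was 9.36 CPM. col-94 (slope -1.25), col-179 (-1.13), C02E7.7 and F56A4.3 also fell, as did col-124, col-19, col-119 and col-140, which were markers used to name the class. F59C12.4 rose by 0.59 per day (standard error 0.07, adjusted p = 0.0429), from 41.1 to 2780 CPM. In all, 2 genes rose and 24 fell among 10688 tested. On day 1, 83.6% of hypodermal cells came from a single cluster led by collagen genes, and other clusters held most of them on the later days.

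Of 114 cuticle collagens in the hypodermis 11 fell and 0 rose over all genes. Hypodermal collagens numbered 62 that fell and 1 that rose adjusted over the list alone (mean slope -0.64, camera adjusted p = 6.36e-46; adjusted p = 0.49 with an estimated correlation). Of 20 glycolysis genes 0 passed by edgeR over all genes and 13 fell adjusted over the list alone, with ldh-1, pck-1 (1414 and 87.3 CPM on days 1 and 11), gpd-2 and enol-1 at the smallest p (mean slope -0.16, camera adjusted p = 5.15e-07; adjusted p = 0.49 with an estimated correlation). The 47 respiratory chain genes had a mean slope of -0.10 with 0 members past either adjustment (camera adjusted p = 4.34e-06; adjusted p = 0.50 with an estimated correlation). Of 19 TCA cycle genes 6 fell adjusted over the list alone (mean slope -0.12, camera adjusted p = 0.000279, 0.0614 without day 1; adjusted p = 0.58 with an estimated correlation). Translation factors had a mean slope of 0.09 (camera adjusted p = 0.000495, 0.08996 without day 1; adjusted p = 0.72 with an estimated correlation). The mean slope was 0.10 for 67 F-box genes (camera adjusted p = 0.00112, 0.0703 without day 1; adjusted p = 0.53 with an estimated correlation). The F-box slope was 0.0504 in cells of at most 3000 UMIs (camera adjusted p = 0.394). For 79 ribosomal proteins the mean slope was 0.05 (camera adjusted p = 0.0134; adjusted p = 0.85 with an estimated correlation), and -0.0167 without day 1. The hypodermal gene count was 214 without day 1, 1 without day 3 and, by edgeR, 0 without day 8 or day 11. By edgeR it was also 0 with library size only (2134 genes at an unadjusted p under 0.05) and with the log2 of the age (2057). It was 0 too with the 5 called doublets kept and all cells clustered and named anew (1585). DESeq2 called 648 and limma-trend 118.

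Some cuticle collagen genes also fell in seam cells. col-94 fell from 1289 CPM to 0 (slope -1.90, adjusted p = 0.00364, n = 5 harvests) and col-93, col-129 and col-139 also fell to 0, with a floor of 33.3 CPM on day 11. gst-19, a glutathione S-transferase gene, fell from 2022 CPM to 0 (slope -2.28, standard error 0.24, adjusted p = 0.00727). F44A2.3 (slope 0.48), the phosphoglycolate phosphatase gene pgph-2 (0.48) and C18D11.6 (0.38) rose. Of 62 cuticle collagens 31 fell, among them col-160, col-20 (46903 CPM to 0), col-179 and col-80. Seam collagens numbered 46 that fell adjusted over the list alone (camera adjusted p = 2.43e-48; adjusted p = 0.49 with an estimated correlation). Of 22 glutathione S-transferases gst-19, gst-7, gst-10 and gst-5 fell, and 11 fell adjusted over the list alone (mean slope -0.40, camera adjusted p = 3.08e-07; adjusted p = 0.56 with an estimated correlation). Of 20 glycolysis genes 10 fell adjusted over the list alone (mean slope -0.18, camera adjusted p = 4.39e-06; adjusted p = 0.53 with an estimated correlation), and of 18 TCA cycle genes 1 did (camera adjusted p = 0.000495; adjusted p = 0.49 with an estimated correlation). Ribosomal proteins had a mean slope of 0.05 (camera adjusted p = 0.00072; adjusted p = 0.81 with an estimated correlation) that was -0.0337 without day 1. In all, 131 genes passed among 8624 tested, 7 of them rising. This count was 54 without day 1 and, by edgeR, 0 without day 8 or day 11. With library size only 19 rose and 42 fell, and the median slope of all genes was 0.1275 per day against -0.013 with TMM. On day 1, 99.7% of seam cells came from a single cluster, and another cluster held most of them later.

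**Figure D4:**
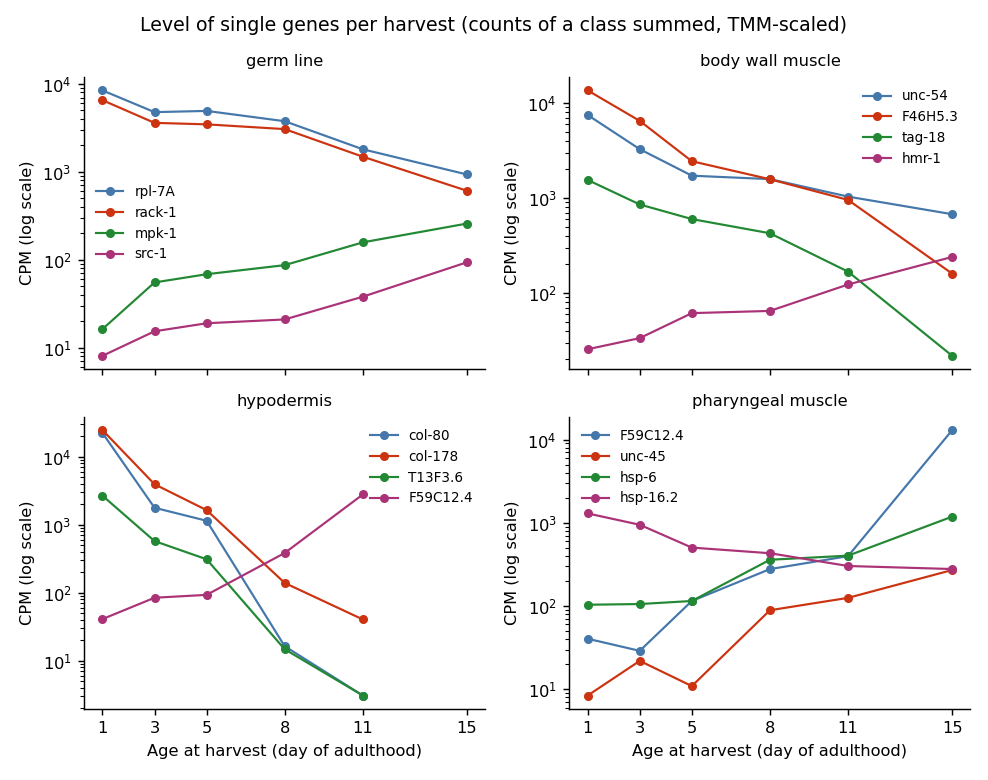
Level (CPM, log scale) of 4 genes each in germ line-like cells, body wall muscle, hypodermis and pharyngeal muscle against age at harvest (day of adulthood), 1 point per harvest from summed counts scaled by TMM. rpl-7A goes from 8432 to 933 CPM in germ line-like cells, and F59C12.4 goes from 40.4 to 12980 CPM in pharyngeal muscle.

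In the pharynx, the mitochondrial chaperone genes hsp-6 and hsp-60 rose and some small heat shock protein genes fell. hsp-6, the mitochondrial HSP70 gene, rose from 103 to 1185 CPM in pharyngeal muscle (slope 0.26, adjusted p = 0.00942, n = 6 harvests) and from 118 to 459 CPM in pharyngeal epithelium and marginal cells (slope 0.15, adjusted p = 0.0272). hsp-16.2, a heat-inducible small heat shock protein gene, fell from 1294 to 278 CPM in the muscle (slope -0.16, adjusted p = 0.0316) and from 2195 to 30.6 CPM in the epithelium (slope -0.39, adjusted p = 0.00832). In the muscle, unc-45 (WBGene00006781), a chaperone for myosin, rose by 0.35 per day (standard error 0.05, adjusted p = 0.00906), from 8.41 to 271 CPM. F59C12.4 rose from 40.4 to 12980 CPM (slope 0.60), and the Fat-like cadherin gene cdh-3 (0.48), gasr-8 (0.44) and the kinesin gene bmk-1 (0.37) rose with it. col-20, col-19, col-124, R05D8.7 and gst-10 (slope -0.95) fell to 0 CPM on day 15, with a floor of 21.9 CPM. In the epithelium, C01G10.4 rose from 237 to 7452 CPM (slope 0.32), and F32A5.3, F23A7.8, B0238.11 and srt-30 rose. F23A7.8 and B0238.11 were at 13.6 and 19.4% of their level in germ line-like cells. F32A5.3 and srt-30 were at 96.9 and 76.4% of that in pharyngeal muscle, and C01G10.4 was highest in the epithelium. col-19, nlp-64, Y45F10D.2, the acid phosphatase gene acp-6 and K02D7.1 fell to 0, with a floor of 45.9 CPM. There col-19 was at 11.7% of its level in seam cells, nlp-64 at 10.1% of that in neurons and acp-6 at 13.1% of that in hypodermis. Y45F10D.2 was at 63.1% of its level in pharyngeal muscle and K02D7.1 at 22.4% of that in the intestine. Whether RNA from other cells entered the levels of these pharyngeal genes was not tested. In all, 236 genes rose and 465 fell among 5471 tested in the muscle, and 70 rose and 335 fell among 5419 in the epithelium.

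Of 42 respiratory chain genes in pharyngeal muscle 21 fell, and adjusted over the list alone 27 fell and 1 rose (mean slope -0.12, camera adjusted p = 1.75e-08; adjusted p = 0.62 with an estimated correlation). In the epithelium 15 of 42 fell, among them asg-2, cox-6B, atp-4 and asb-2. There 26 fell adjusted over the list alone (camera adjusted p = 5.62e-09; adjusted p = 0.49 with an estimated correlation). In the muscle 9 of 18 glycolysis genes fell, and 10 adjusted over the list alone (camera adjusted p = 8.83e-05; adjusted p = 0.62 with an estimated correlation). Of 18 TCA cycle genes 6 fell, and 8 adjusted over the list alone (camera adjusted p = 0.00105, 0.0693 without day 1; adjusted p = 0.67 with an estimated correlation). Of 6 mitochondrial unfolded protein response genes in the muscle hsp-6 and hsp-60 rose, the same number as adjusted over the list alone (camera adjusted p = 0.0364; adjusted p = 0.50 with an estimated correlation). Its camera adjusted p was 0.101 without day 5, 0.0673 without day 8 and 0.220 without day 15. In the epithelium hsp-60 (12.1 to 138 CPM) and hsp-6 rose among 9, the same number as adjusted over the list alone (camera adjusted p = 0.00615, 0.0993 without day 15; adjusted p = 0.49 with an estimated correlation). Of 23 chaperones in the muscle unc-45 and cct-3 rose, the same number as adjusted over the list alone (mean slope 0.06, camera adjusted p = 0.0081, 0.0575 without day 1; adjusted p = 0.52 with an estimated correlation). Of 12 small heat shock proteins 4 fell in the muscle over all genes and adjusted over the list alone (camera adjusted p = 0.0118, 0.0739 without day 15; adjusted p = 0.50 with an estimated correlation). In the epithelium hsp-16.41 (slope -0.42, 1276 to 15.3 CPM), hsp-16.2 and hsp-43 fell. There 4 fell adjusted over the list alone (camera adjusted p = 2.55e-05; adjusted p = 0.49 with an estimated correlation). Of 44 sarcomere genes in the muscle tni-3, zyx-1 and 1 other fell while unc-89 (513 to 2435 CPM), ttn-1 (867 to 4856 CPM) and 1 other rose. Adjusted over the list alone 5 fell and 3 rose, and the list did not pass camera (adjusted p = 0.194, 0.0280 without day 3).

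Ribosomal protein genes had mean slopes of 0.06 in pharyngeal muscle, where rps-28, rpl-24.2 and rpl-39 rose over all genes and 0 by edgeR adjusted over the list alone (camera adjusted p = 0.000164, 0.739 without day 1; adjusted p = 0.78 with an estimated correlation). The slope was 0.03 in the epithelium (camera adjusted p = 3.23e-05, 0.812 without day 1; adjusted p = 0.78 with an estimated correlation). The muscle count of 701 genes was 88 without day 1, 202 without day 3, 155 without day 11 and 75 without day 15. The epithelial count of 405 was 267 without day 1, 181 without day 3, 49 without day 11 and 64 without day 15. With library size only, 440 genes rose and 284 fell in the muscle and 244 rose and 234 fell in the epithelium.

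In the intestine, some vitellogenin, cathepsin and glutathione S-transferase genes fell with age. vit-1, a vitellogenin gene, fell from 2333 CPM to 0 by day 11, where the floor was 73 CPM, and asp-3, an aspartyl protease gene, fell from 2076 to 48.7 CPM. T19D12.4 (slope 0.48, adjusted p = 0.0137), F23A7.8 (0.45) and the saposin-like gene spp-21 (0 to 243 CPM) rose. Of 6 vitellogenins vit-1, vit-3 and vit-4 fell, and 6 fell adjusted over the list alone (mean slope -0.59, camera adjusted p = 5.81e-07, n = 5 harvests; adjusted p = 0.49 with an estimated correlation). Of 19 cathepsins asp-3 and asp-14 fell, and 6 adjusted over the list alone (camera adjusted p = 0.000975; adjusted p = 0.62 with an estimated correlation). Of 24 glutathione S-transferases gst-10, gst-19, gst-28 and gst-4 fell. These transferases numbered 14 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 3.03e-07; adjusted p = 0.50 with an estimated correlation). Of 44 lysozymes and antimicrobial peptides 6 fell and 1 rose, with fipr-22, lys-4, ilys-5 (5055 and 24.3 CPM on days 1 and 11) and cnc-11 at the smallest p. In that list 22 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00353, 0.178 without day 8; adjusted p = 0.61 with an estimated correlation). Of 13 fatty acid synthesis genes elo-6 fell, and 5 adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.58 with an estimated correlation). The 52 mitochondrial ribosomal proteins had a mean slope of 0.12 (camera adjusted p = 0.00028; adjusted p = 0.74 with an estimated correlation), and the 79 cytosolic ribosomal proteins of 0.05 (camera adjusted p = 0.00623; adjusted p = 0.82 with an estimated correlation).

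The intestine had 8 rising and 118 falling genes among 7359 tested. The falls were led by col-80, col-139, col-124, col-129 and col-19, cuticle collagens whose levels in intestinal cells were 10.78 to 12% of those in the class where each was highest. The count of 126 was 38 without day 1, 41 without day 3, 35 without day 8 and, by edgeR, 0 without day 11, whose intestinal cells held 30730 UMIs. With library size only 19 genes rose and 68 fell.

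**Figure D5:**
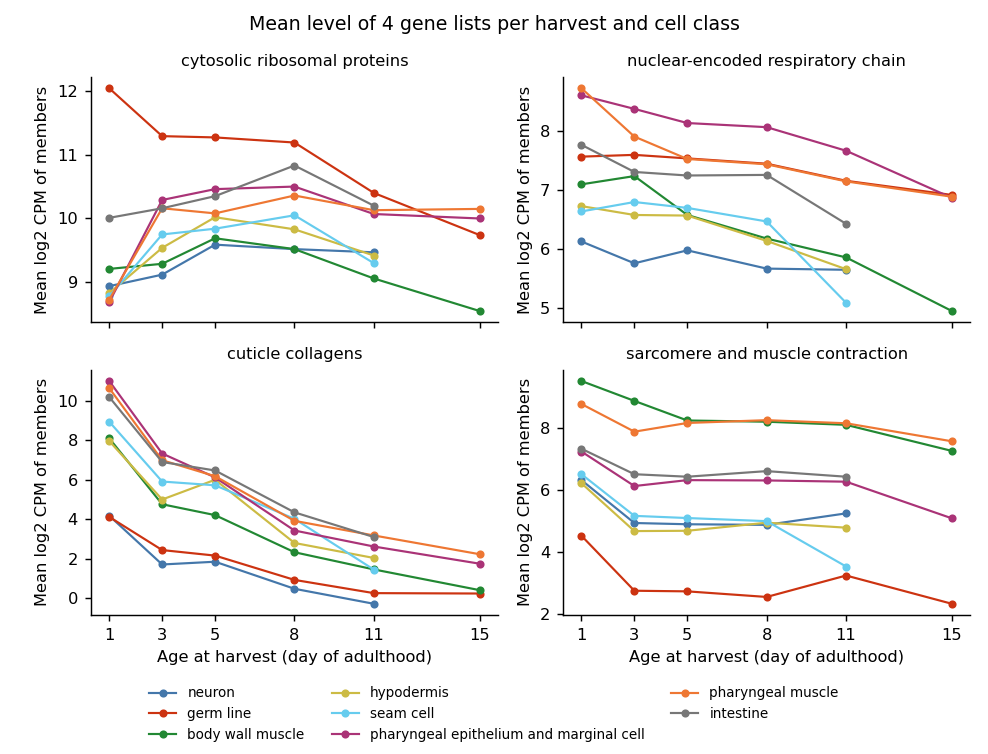
Mean log2 CPM of the members of 4 gene lists (vertical axes) against age at harvest (day of adulthood), with a line per cell class and 1 harvest per age. In germ line-like cells the cytosolic ribosomal proteins go from 12.04 on day 1 to 9.74 on day 15, a list call with an adjusted p of 0.50 under an estimated correlation.

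In neurons no gene passed the trend test. The leading neuron cluster changed between harvests, from a cluster with 26.6% of the neurons on day 1 to others on day 3, on days 5 and 8 and on day 11. By edgeR 0 of 15426 genes passed, with 2396 at an unadjusted p under 0.05. DESeq2 called 181 rising and 565 falling genes and limma-trend 0, and edgeR called 28 without day 3. The genes with the smallest p were ZK54.3 (316 CPM on day 1 and 29.2 on day 11, slope -0.33, standard error 0.04, adjusted p = 0.0815, n = 5 harvests), gst-10 (slope -0.66), gst-28 (slope -0.57), linc-5 (slope 0.22), F23A7.4 (slope 0.21) and byn-1, the bystin gene of ribosome assembly (slope 0.19, adjusted p = 0.139). The 57 genes of cilia and intraflagellar transport had a mean slope of -0.17 with 0 members past either adjustment, and che-13 was at 60.3 CPM on day 1 and 6.3 CPM on day 11 (camera adjusted p = 2.78e-10; adjusted p = 0.66 with an estimated correlation). Of 20 glycolysis genes 14 fell adjusted over the list alone and 0 by edgeR over all genes, with tpi-1 (600.1 and 138 CPM), pgk-1, ipgm-1 and gpd-2 at the smallest p (camera adjusted p = 1.54e-08; adjusted p = 0.49 with an estimated correlation). Of 23 ER chaperone and unfolded protein response genes 7 fell adjusted over the list alone, with hsp-4 (1863 and 192 CPM), pdi-6, cup-2 and enpl-1 at the smallest p (camera adjusted p = 0.00103, 0.257 without day 1; adjusted p = 0.69 with an estimated correlation). Of the 12 genes of the mitochondrial genome 9 fell adjusted over the list alone (camera adjusted p = 3.92e-06, 0.0782 without day 1; adjusted p = 0.61 with an estimated correlation).

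Ribosomal proteins in neurons had a mean slope of 0.05 (80 genes, camera adjusted p = 2.04e-06; adjusted p = 0.74 with an estimated correlation), and translation factors 0.05 (camera adjusted p = 0.00218, 0.113 without day 1; adjusted p = 0.68 with an estimated correlation). Genes of synaptic vesicle release did not pass camera (27 genes, mean slope -0.02, adjusted p = 0.528, 0.0455 without day 11), and neither did neuropeptides (110 genes, mean slope -0.08, adjusted p = 0.0690). Neuropeptides passed without day 3 (0.0262) or without day 8 (0.00109); 8 neuropeptide genes fell adjusted over the list alone.

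Of the 13 genes followed in every class because of the strain or the literature on ageing, some changed in at least 1 class. daf-16, the FOXO factor of insulin signalling, rose in germ line-like cells from 54.2 to 126 CPM (slope 0.08, adjusted p = 0.0174), and skn-1, the Nrf factor of the oxidative stress response, from 27.1 to 167 CPM (slope 0.13, adjusted p = 0.0129). hsp-4, the BiP gene of the ER, fell in the intestine from 1024 to 24.3 CPM (slope -0.46, adjusted p = 0.0265) and in germ line-like cells from 306 to 146 CPM (slope -0.08, adjusted p = 0.0415). eef-1A.1, a translation elongation factor gene, fell in germ line-like cells from 22780 to 2885 CPM (slope -0.20, adjusted p = 0.0101). vit-2 was at 8815 CPM on day 1 and 1947 CPM on day 11 in the intestine (slope -0.23, adjusted p = 0.146); it passed the test in body wall muscle and in both pharyngeal classes, at levels of 0.970 to 2.03% of the intestinal one. gon-2 did not pass in any class by edgeR, its highest level being in pharyngeal muscle with 303 CPM on day 1 and 1338 CPM on day 15 (slope 0.13, adjusted p = 0.165). daf-2, hsf-1, hlh-30 and sod-3 did not pass in any class tested, and in the hypodermis daf-2 was at 18.9 CPM on day 1 and 99.8 CPM on day 11 (adjusted p = 0.207) and sod-3 at 52.2 and 3.12 CPM (adjusted p = 0.0882).

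Across classes, cuticle collagens were the genes that fell most widely. col-119, col-140, col-124, col-178 and col-19 fell in 7 of the 8 classes, and col-101, col-181, col-122, col-184 and gst-10 in 6. In all, 105 genes fell and 7 rose in at least 4 classes. The 7 were T23G7.3, T23D8.3, byn-1, the leucyl-tRNA synthetase gene lars-1, K07A12.1, the S6 kinase gene rsks-1 and asna-1, each in 4 classes; crn-3, C18D11.6 and the RNA polymerase II subunit gene rpb-2 rose in 3. The collagens were far below the epidermal level in most of these classes: as a list, the median level was 0.165% of that in the highest class in germ line-like cells, where 22 of 43 fell over all genes and 24 adjusted over the list alone (camera adjusted p = 1.21e-10; adjusted p = 0.50 with an estimated correlation). It was 2.05% in body wall muscle, where 27 of 33 fell and 29 adjusted over the list alone (camera adjusted p = 1.19e-29; adjusted p = 0.49 with an estimated correlation). In pharyngeal muscle it was 7.38% (19 of 20 fell by either adjustment, and the list adjusted p was 0.49 with an estimated correlation), in the pharyngeal epithelium 6.63% (19 of 19, adjusted p = 0.49 with an estimated correlation) and in the intestine 9.25% (23 of 32, 27 adjusted over the list alone, adjusted p = 0.49 with an estimated correlation). Without days 11 and 15 no gene passed in 4 classes by edgeR.

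In a joint fit, the slopes of 25 genes differed between neurons and germ line-like cells by edgeR, 20 with the higher slope in germ line-like cells. dmd-9, a DM-domain gene, had a slope higher by 0.64 in germ line-like cells (standard error 0.11, adjusted p = 0.000213), with slopes of -0.52 in neurons and -0.07 in germ line-like cells fitted alone, and akt-1, an insulin pathway kinase gene, a slope higher by 0.39 (adjusted p = 0.0317), with -0.18 and 0.09. For nlp-20 the joint difference of 0.30 had the opposite sign to the slopes fitted alone (0.09 in neurons and -0.04 in germ line-like cells). The count of 25 was 1 without day 1, 0 without day 3 (1864 at an unadjusted p under 0.05) and 11 without day 8, 1 with RLE size factors and 683 with the log2 of the age. Between body wall muscle and hypodermis, fmo-2, a flavin monooxygenase gene named after its value was seen, differed by -1 (adjusted p = 0.0273). That count was 11 without day 1, 22 without day 3 and, by edgeR, 0 without any of days 5, 8 and 11. For the other pairs edgeR called 0, with 1114 genes at an unadjusted p under 0.05 for neurons against body wall muscle, 1659 for neurons against hypodermis, 1385 for germ line against body wall muscle and 1492 for germ line against hypodermis. The second was 145 without day 3, the third 80, 58 and 30 without days 1, 5 and 8, and the fourth 295, 245 and 4 without days 1, 3 and 8.

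None of 227 list differences between classes passed after adjustment. All pairs except germ line against body wall muscle had 5 harvests, where the 120 orders allow no exact p under 0.00833. Over 227 tests that left little room for a difference to pass. The smallest exact permutation p was 0.00139 (adjusted p = 0.105, n = 6 harvests), for the TCA cycle, collagens and vitellogenins between germ line and body wall muscle, and 52 had an unadjusted p under 0.05. The ribosomal protein slope differed by 0.187 between neurons and germ line-like cells (exact permutation p = 0.025, adjusted p = 0.153, n = 5 harvests). It differed by -0.098 between germ line and body wall muscle (exact permutation p = 0.0208, adjusted p = 0.153). A difference between classes was thus neither shown nor excluded.

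Fold changes of named genes against day 1 are given by day, and a difference in timing between genes was not tested. In the hypodermis, col-80 was lower by day 3 (log2 fold change -3.68, adjusted p = 0.000111) and at -12.87 on day 11, and col-178 was at -2.67 and -9.34. In body wall muscle F46H5.3 was at -0.96 on day 3, -2.46 on day 5 and -6.31 on day 15, and hmr-1 at 0.49, 1.29 and 3.33. In germ line-like cells rpl-7A was at -0.76 on day 3, -2.15 on day 11 and -3.15 on day 15, and mpk-1 at 1.82, 3.34 and 4.01. There src-1 (0.97 and 1.28 on days 3 and 5) and gly-9 (-0.31 and 0.04) did not pass on day 3, 5 or 8 by edgeR. Higher and lower genes numbered 1179 and 420 on day 3 in germ line-like cells. They numbered 1221 and 881 on day 3 in body wall muscle. In the hypodermis they numbered 1873 and 1282 on day 3 and 1114 and 1646 on day 11, and in neurons 2119 and 1393 on day 3 and 2075 and 2878 on day 11. Day 15 was a single channel, so genes that passed on that day are not counted here. DESeq2 split the germ line count otherwise, with 690 higher and 864 lower on day 3. In the hypodermis it gave 1312 higher and 1495 lower on day 3, 1954 and 2418 on day 5 and 1412 and 1945 on day 8. These tests share 1 estimate of the spread between channels, drawn from the days with 2 channels, since day 15 had 1. They say nothing about the spread between populations. Without channel 1 of day 1 the germ line counts were 1021 on day 3 and 1252 on day 5, against 1599 and 1911.

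The number of genes detected per cell showed no trend that passed. In cells thinned to 300 UMIs its slope was 1.62 genes per day in germ line-like cells (exact permutation p = 0.0139, adjusted p = 0.111, n = 6 harvests) and -1.03 in body wall muscle (exact permutation p = 0.0333, adjusted p = 0.133).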

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

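The tests on orders of the ages, on RNA from other cells, on the share outside the neuron class and in cells of at most 3000 UMIs were chosen after the results or the data were seen; the others in this part were planned. Trends that differed between classes by a test of the difference itself were singled out here. They were 25 genes between neurons and germ line-like cells and 1 gene between body wall muscle and hypodermis. The slope was higher in germ line-like cells than in neurons by 0.64 log2 per day for dmd-9, by 0.41 for cblc-1, by 0.42 for R02D3.8 and by 0.39 for akt-1, and the difference was -0.48 for F52D2.14. The slope of fmo-2 differed by -1 between hypodermis and body wall muscle, at levels of 1.99% and 0.278% of that in its highest class. Of 100 orders of the ages, 8 gave at least as many differing genes between neurons and germ line-like cells as the real 25, with 221 as the highest other, so chance cannot be excluded for that count. Why another order gave several times as many was not tested.

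The share of germ line-like cells was larger in later harvests, although its adjusted p of 0.121 did not pass. If fewer captured neurons were the whole reason, the share among the other cells would stay level. Its slope there was 0.255 per day on the logit scale (exact permutation p = 0.0319, adjusted p = 0.120). By the unadjusted p this argues against a shrinking neuron share as the whole reason, but the slope did not pass after adjustment, so the question is not settled. Droplets that took up RNA from other cells cannot be told apart from germ cells by these levels: over 24 markers the median level in neurons was 3.73% of that in germ line-like cells, but the same markers had named the cells. What also stays open is whether germ cells grew in number, whether later worms released them more readily, or whether other cells were lost, and the age of the worms itself was not separated from these.

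Of the genes that fell in at least 4 classes, 18.1% (19 of 105) still did when only classes at 0.1 or more of the highest class's level were counted. Most of the others reached that level in fewer than 4 classes, so they could not be counted whatever their slopes. A candidate explanation for the rest is RNA from other cells, such as epidermal collagen transcripts carried into the droplets of other classes: falling levels there may reflect the fall in their source. Without day 1 the median slope of 422 gene and class pairs was 0.889 of that with it, so the median fall did not rest on day 1 alone. Whether a different mix of clusters on day 1 added to the falls cannot be decided from that median, since it pools classes. In the pharyngeal epithelium and the intestine a single cluster held all cells on every day. In hypodermis and seam cells the cluster with 83.6% and 99.7% of the day 1 cells led on no later day. Age itself stays open as untested for the genes that fell in at least 4 classes.

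Cytosolic ribosomal protein genes fell in germ line-like cells under the test with a preset correlation (adjusted p = 0.50 with an estimated correlation). Scaling was argued against as the whole reason, since the mean slope nearest to 0 under other scalings was -0.108, and so was a single harvest, since the mean slope was -0.132 without day 15. Shallower cells on days 11 and 15 cannot be told apart from age: in cells of at most 3000 UMIs the mean slope was -0.086, between the bounds set beforehand for either reading. The largest cluster of the class held 67.2% of its cells on day 1, 54.85% on day 5, 76.6% on day 11 and 78.1% on day 15. Whether the later cells are of another kind of germ cell was not tested.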

How the results depend on the processing

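The alternatives with at least 1000 UMIs per cell, at most 3000 UMIs per cell, the highest doublet scores removed, days 11 and 15 left out, and, for shares, at most 15% mitochondrial UMIs and cells outside the neuron class were added after seeing the data; all others were planned. The minimum of 500 UMIs removed no cell and so tested nothing. Except where a sentence names a cause, the cause was not tested. Single genes kept direction and side of the threshold in 572 of 581 cases with RLE factors, 524 with library size only, 536 with limma-trend and 476 with DESeq2, where 103 others passed and 2 no longer did. With days 11 and 15 left out 305 no longer passed and 270 did not change side. Cases that passed in neither fit count as unchanged, whatever their direction, in these figures and in those for lists. Few genes passed in any class without days 11 and 15, so most of the 270 had not passed with all harvests either. Lists described in the text kept their call in 68 of 68 cases with RLE factors, 62 with library size only and 63 with the log2 of the age, while 64 lost it with an estimated correlation. Without the naming markers of a class 67 described lists did not change side. No class share passed in any leave-one-out. For neurons without day 8 the exact permutation p was 0.00833, the smallest that 120 orders allow, and the adjusted p was 0.133. Leaving out a harvest therefore left little room for a share to pass.

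Counts of trending genes (0 in neurons, 1403 in germ line-like cells, 528 in body wall muscle, 26 in hypodermis, 131 in seam cells, 405 in pharyngeal epithelium, 701 in pharyngeal muscle and 126 in intestine) moved as follows. With no filter on low counts they were 29 in neurons, 210 in hypodermis, 594 in seam cells and 951 in intestine. DESeq2 gave 746 in neurons, 2442 in germ line, 965 in body wall muscle, 648 in hypodermis, 398 in seam cells, 647 in pharyngeal epithelium and 457 in intestine. limma-trend gave 1142 in body wall muscle, 118 in hypodermis, 795 in pharyngeal epithelium and 297 in intestine. The log2 of the age gave 37 in neurons, 221 in body wall muscle, 0 in hypodermis, 210 in seam cells, 105 in pharyngeal epithelium and 429 in pharyngeal muscle. With library size only they were 2296 in germ line, 0 in hypodermis and 61 in seam cells, and with RLE factors 51 in hypodermis and 210 in intestine. The median slope of all genes with library size only, against that with TMM, was 0.0366 and -0.0038 in germ line, 0.0384 and -0.0176 in body wall muscle, 0.0808 and 0.0044 in hypodermis and 0.1275 and -0.013 in seam cells.

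The 3 younger against the 3 older harvests gave 0 genes by edgeR in every class with a count except pharyngeal epithelium, with 19. Leaving out days 11 and 15 gave 0 in germ line, body wall muscle, hypodermis, seam cells, pharyngeal muscle and intestine and 20 in pharyngeal epithelium; fewer harvests and a shorter age range enter there by construction. Leaving out each harvest in turn gave 0 to 28 in neurons, 0 to 2959 in germ line, 58 to 480 in body wall muscle, 0 to 214 in hypodermis, 0 to 130 in seam cells, 49 to 508 in pharyngeal epithelium, 75 to 847 in pharyngeal muscle and 0 to 117 in intestine. Leaving out the first or the second channel of every harvest gave 7 to 1354 in germ line, 43 to 456 in body wall muscle, 9 to 43 in hypodermis, 29 to 310 in pharyngeal epithelium, 156 to 159 in seam cells, 26 to 418 in pharyngeal muscle and 0 to 4 in intestine; without the first, day 15 is lost by construction.

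With channels as samples and no replicate block the counts were 3288 in neurons, 2985 in germ line, 1984 in body wall muscle, 1673 in hypodermis, 1142 in seam cells, 1025 in pharyngeal epithelium, 1308 in pharyngeal muscle and 1075 in intestine, since technical spread stands in for that between harvests. With a replicate block they were 2593, 2682, 1758, 1393, 970, 928, 1160 and 714 in the same order. Channels with the same number had correlations of -0.181 to 0.306 between harvests, the highest being 0.306 in germ line-like cells and 0.229 in body wall muscle. Whether they shared more than the number was not tested. Counts thinned to the smallest harvest, which have less depth by construction, gave 0 in germ line, 1 in body wall muscle, 8 in seam cells, 5 in pharyngeal epithelium, 36 in pharyngeal muscle and 0 in intestine; there the slope of pgk-1 in body wall muscle was 0.0091 and that of atp-4 in pharyngeal epithelium 0.0026, both opposite to the main sign.

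At least 1000 UMIs per cell gave 3 in neurons and 0 in intestine. At most 3000 UMIs per cell gave 315 in body wall muscle, 47 in hypodermis and 201 in seam cells. Keeping the called doublets, with all cells clustered and named anew, gave 0 in hypodermis. Coarser clustering gave 40 in hypodermis and 203 in intestine. Testing only genes at 0.1 or more of the highest class gave 81 in hypodermis and 265 in seam cells. The slope of rrn-4.2 in germ line was -0.0923 with days 11 and 15 left out, against 0.44.

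Lists past the threshold numbered 15 to 25 in neurons, 10 to 20 in hypodermis, 10 to 18 in seam cells and 11 to 17 in pharyngeal muscle when each harvest was left out in turn, the lowest without day 1, against 23, 17, 17 and 17. With an estimated correlation 0 passed in each of the 8 classes, and by fry 1 each in germ line, pharyngeal epithelium and pharyngeal muscle and 0 in neurons, body wall muscle, hypodermis, seam cells and intestine. Cytosolic ribosomal proteins had a slope of 0.0234 in body wall muscle with library size only. Leaving out each harvest in turn gave slopes of -0.0167 to 0.1222 for the list cytosolic ribosomal proteins in hypodermis and -0.0337 to 0.1502 for the list cytosolic ribosomal proteins in seam cells, both negative without day 1. In cells of at most 3000 UMIs translation factors had a slope of 0.0098 and mitochondrial ribosomal proteins of 0.0288 in germ line.

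The genes that differed between neurons and germ line, 25, were 683 with the log2 of the age, 1 with RLE factors and 0 to 31 when a harvest was left out. That range was 0 to 145 for neurons against hypodermis, 0 to 80 for germ line against body wall muscle, 0 to 295 for germ line against hypodermis and 0 to 22 for body wall muscle against hypodermis; with the log2 of the age the last pairs gave 1 and 2. Leaving out 1 channel in turn gave germ line counts of 1021 to 1672 on day 3 and 1252 to 1987 on day 5, and hypodermis counts of 1963 to 3309 on day 3 and 1707 to 2723 on day 11. DESeq2 gave 1187, 1399, 1319 and 1769 in body wall muscle on days 3, 5, 8 and 11. The genes shared by several classes, 7 rising and 105 falling, were 229 in at least 3 classes and 0 with days 11 and 15 left out. The logit slope of pharyngeal gland cells was 0.3423 and passed with the highest doublet scores removed, and that of genes per cell in pharyngeal muscle was -18.07 and passed without thinning, where depth per cell enters by construction.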

Other observations

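The orders of the ages described last in this part were tested after the results were seen; the list tests were planned. In pharyngeal muscle, 40 of 84 neuropeptide genes fell over all genes and 54 adjusted over the list alone (mean slope -0.32, camera adjusted p = 3.16e-21; adjusted p = 0.49 with an estimated correlation), at a median of 10.0% of the level in the highest class. Of 33 lysozymes and antimicrobial peptides in pharyngeal muscle 13 fell and 1 rose, and adjusted over the list alone 18 fell and 1 rose (camera adjusted p = 1.88e-07; adjusted p = 0.49 with an estimated correlation). Of 19 genes of the vacuolar proton ATPase, the pump that acidifies lysosomes, 5 fell in pharyngeal muscle, and adjusted over the list alone 11 fell and 1 rose (mean slope -0.10, camera adjusted p = 0.00072; adjusted p = 0.62 with an estimated correlation). In the intestine 13 of 20 such genes fell adjusted over the list alone and 0 by edgeR over all genes (mean slope -0.17, camera adjusted p = 0.000123; adjusted p = 0.62 with an estimated correlation).

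Glutathione S-transferases passed camera as falling in all 8 classes, with mean slopes of -0.18 to -0.40; the adjusted p was 0.4865 to 0.62 with an estimated correlation. Adjusted over the list alone, 14 of 42 fell in neurons, where edgeR called 0 over all genes, and 11 of 17 in pharyngeal muscle, where 6 fell over all genes. In body wall muscle, of 6 pals genes, a family induced by intracellular pathogens, 1 rose over all genes and 2 adjusted over the list alone (mean slope 0.11, camera adjusted p = 0.0361; adjusted p = 0.64 with an estimated correlation). Of 33 genes of fatty acid oxidation in body wall muscle 3 fell over all genes and 5 adjusted over the list alone (mean slope -0.11, camera adjusted p = 0.0111; adjusted p = 0.61 with an estimated correlation).

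The number of trending genes was set against 100 orders of the ages, the real one included. In germ line-like cells 1 of the 100, the real one with 1403 genes, gave as many, and the highest other gave 45. In body wall muscle it was 1, with 528 against 85, and in hypodermis 1, with 26 against 1. In pharyngeal epithelium it was 1, with 405 against 90, and in pharyngeal muscle 1, with 701 against 160. These counts exceeded every other order drawn, and 1 in 100 is the smallest share that 100 orders allow. Orders of the ages cannot separate age from depth or cell number, which also changed along the series. In the intestine 3 of the orders gave at least the real 126. The highest other gave 173, more than the real one, so chance is not excluded by that share. In seam cells 7 gave at least the real 131, with 585 as the highest other, so chance cannot be excluded there. Why another order gave several times as many was not tested. In neurons all 100 gave at least the real 0. These shares of orders were not adjusted over the 8 classes. For genes shared by at least 4 classes 1 order gave as many as the real 7 rising and 105 falling together, with 37 as the highest other. For the 105 falling genes alone it was 1, with 3 as the highest other, so no other order drawn came near that count. For the 7 rising genes alone 5 orders gave as many, with 36 as the highest other, so chance cannot be excluded for these. For gene lists 3 orders gave as many as the real 146, with 149 as the highest other, but the median of the other orders was 11 to 15 lists per class against the real 16 to 23, so an order of the ages taken at random already passed most of that number. By class, 3 orders gave at least the real 18 lists in body wall muscle, with 18 as the highest other. Another order tied with the real one and the share was not adjusted over the 8 classes, so chance is not excluded. Nor can chance be excluded in neurons (10 orders, 23 lists against 25 as the highest other), germ line (6, 17 against 17), hypodermis (27, 17 against 22), seam cells (16, 17 against 20), pharyngeal epithelium (13, 16 against 18), pharyngeal muscle (23, 17 against 21) and intestine (6, 21 against 24).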
